A study of Drosophila melanogaster with 3 samples.

How the data were processed

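Peaks of a GFP-tagged protein were listed by the authors for 3 biological replicates (1, 2 and 4) of whole embryos, immunoprecipitated with an anti-GFP antibody after sonication to 200 to 800 bp. Per the labels each replicate came from its own biosample of the same line, and the protocol documents attached to the replicates differ. The replicate lists, a pooled list and an optimal list were deposited in the dm6 and dm3 builds. Per the deposited inventories, the pooled list was derived from the 3 alignments with a single control, and the optimal list from the 3 replicate lists and the pooled list by irreproducible discovery rate. The caller, aligner and rate threshold are not given in the sources used here. The signal column holds the signal value per region that the authors' caller gave, on each list's own scale, with no stated normalization. The deposited column 9 holds a −log10 q value as given by the authors, which was 2.90 at the lowest optimal peak. Read counts were not used here, so depth per replicate is unknown, and intervals cover counting of peaks or genes only.

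The dm6 lists were used for all comparisons, with the summit as the position of a region and signal as the rank. The 3 replicates were 1 group. Equal list lengths were used, 5208 regions each, the size of the optimal list, because replicate lists hold peaks and background together. At that rank the signal was 50.2, 52.2 and 56.0 in replicates 1, 2 and 4. Summits within 100 bp were counted as matched and compared with 1000 random circular shifts along each arm (100 shifts for the whole lists, where the smallest p is 0.0099).

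Annotation came from Ensembl release 115 for the dm6 assembly and sequence from the matching RefSeq assembly. The gene set was 13945 protein-coding genes on 6 arms. A summit within 500 bp of a start site was a promoter peak, and classes were assigned in the order promoter, 5' untranslated, coding, 3' untranslated, intron and intergenic. Location was compared with 1000 sets of random positions on the same arms (200 sets in the alternatives), and counts per arm with 1000 placements by arm length. The 21 gene lists were tested with Fisher's exact test and against 10000 random lists matched on gene length in 5 bins and number of start sites. Of 950 listed symbols, 935 gave a gene of their own, 3 were second names of a gene already in the same list, and 12 had no match, namely Tor, Derlin-1, Trib3, Asns, SmG, nos in both of its lists, Dl, E(spl)m1-BFM, n-syb, Trh and Bruno1, which were not analysed here under these symbols. The genes behind nos and n-syb were counted as nanos in the germline list and as nSyb in the neuronal list, where those names were also listed. Some listed symbols were read through synonyms to current names, such as h to hry. Motifs were searched on both strands in windows of 101 bp at the summit and 500 bp to each side. Hexamers had to occur in at least 50 summit windows to be named. A threshold of 0.05 was applied to Benjamini-Hochberg adjusted p. Shares carry 95% Wilson intervals, and a count of 0 is given the limit of 3 counts.

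The comparisons, tests, 21 gene lists, 16 motifs and the rule for named genes were set before the data were examined. The rule took the 20 optimal peaks of highest signal matched in all 3 replicates, REPTOR and REPTOR-BP, and up to 4 genes with the strongest promoter peak from each list that passed or that covered nutrient signalling, autophagy or bZIP factors. Not every gene that the rule took is named in the text. Alternatives were other match distances, list lengths, promoter widths, motif windows and flank distances, stronger peaks, peaks matched in all 3 replicates, matched gene lists, the dm3 list for arms, and each replicate left out. Chosen after the data were seen were the weakest 5000 pooled regions as a reference for location, peaks matched in replicates 1 and 4, arrangements of the same bases for motifs, arm Y left out, random lists also matched on a neighbouring start site within 1000 bp, lists without REPTOR, replicates left out for arms and rank agreement, and 3 gene lists of abundant housekeeping genes, Polycomb and trithorax genes, and translation factors. The spacing of summits around REPTOR-BP was also measured after the data were seen.

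Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 with random seed 7. The statistics were tested on simulated data with planted overlaps, lists and motifs. Expression, untagged controls and read coverage were not analysed here. The dm3 lists were used only for shares per arm and for a count of regions off the main arms.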

Results

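Chromatin immunoprecipitation with an anti-GFP antibody, followed by sequencing, was performed on whole Drosophila melanogaster embryos of mixed sex collected at 0 to 24 h. The labels disagree on the tagged protein. The strain, source and antibody fields name CG18619, which is REPTOR-BP, whereas the description and a note name a C-terminal GFP fused to REPTOR. REPTOR and REPTOR-BP are partner basic leucine zipper (bZIP) transcription factors that act in the response to TORC1 inhibition, and the regions below are called peaks of the tagged protein without a choice between them. The 3 biological replicates, numbered 1, 2 and 4, form 1 group. No untagged, treated or mutant group was among the samples used here, so the comparisons were among replicates, and between peaks and the rest of the genome. Each replicate list held 30000 regions, peaks and background together, and the authors' optimal list held 5208 peaks on the dm6 build. The sequencing depth is unknown, because the lists give no read counts. The question addressed was where in the embryonic genome the tagged protein was found.

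The strongest peaks lay at genes of several kinds. The highest signal was at the promoter of CG14100 (3L, 19590418 to 19590829, signal 4036), followed by the promoter of Ugalt, a UDP-galactose transporter (X, 2703659 to 2704107, signal 3791). An intronic peak of ush whose nearest start site was that of cbt, a zinc finger transcription factor, came next (2L, 480848 to 481339, signal 3751). Intronic peaks of CG11050 (signal 3621), of Trl, which encodes GAGA factor (3002), and of the overlapping HMG-box genes HmgD and HmgZ (2938) were also among the strongest. So were an intronic peak of Lk6, a kinase of the translation initiation factor eIF4E (2622), and the promoter peak of px (2951). The promoter peak shared by Chro, a chromatin protein of interbands, and Ssl1, a subunit of TFIIH, had a signal of 2563, and the one shared by Art3 and mRpS10 had 2557. The remaining peaks of the strongest 20 were at CG4004 (intergenic, 5022 bp from the start site), CG32772, PNPase, mRpL41, CG31145, CG13323 (intergenic, 11917 bp away), hll, CG9663, CG1888 and Tina-1. Of these 20 peaks, 10 lay in promoters, 7 in introns and 3 between genes. Each ranked within the first 26 regions of replicate 1, the first 31 of replicate 2 and the first 70 of replicate 4. Signal values are on the pooled list's own scale and carry no error of their own.

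The replicates placed many of their strongest regions at the same positions. Among the 5208 strongest regions of each list, 74.0% of summits in replicate 1 had a summit of replicate 4 within 100 bp. The share was 62.6% for replicates 1 and 2 and 59.5% for replicates 2 and 4, a mean of 65.3% ± 7.62 (SD, n = 3 pairs, which share replicates). Lists shifted at random along each arm matched at 0.787% on average and at 1.29% at most (one-sided permutation p = 0.0010, the smallest that 1000 shifts can give). The match was 75.8% ± 5.97 for the 1000 strongest regions and 38.2% ± 2.96 for all 30000 (SD, n = 3 pairs). Of the optimal peaks, 82.6%, 70.9% and 81.9% had a match among the 5208 strongest regions of replicates 1, 2 and 4, a mean of 78.4% ± 6.5 (SD, n = 3). In all 3 replicates 2781 peaks were matched (53.4%), in 2 replicates 1610, in 1 replicate 694, and in none 123. Across peaks, which are not independent replicates, Spearman's rho of the signal was 0.811 for replicates 1 and 4 (4672 peaks), 0.686 for 1 and 2 (4573 peaks) and 0.634 for 2 and 4 (4509 peaks). The mean was 0.710 ± 0.0907 (SD, n = 3 pairs). The optimal list was derived from these same replicates, so its match to them and the rho over its peaks are in part built in.

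**Figure D1:**
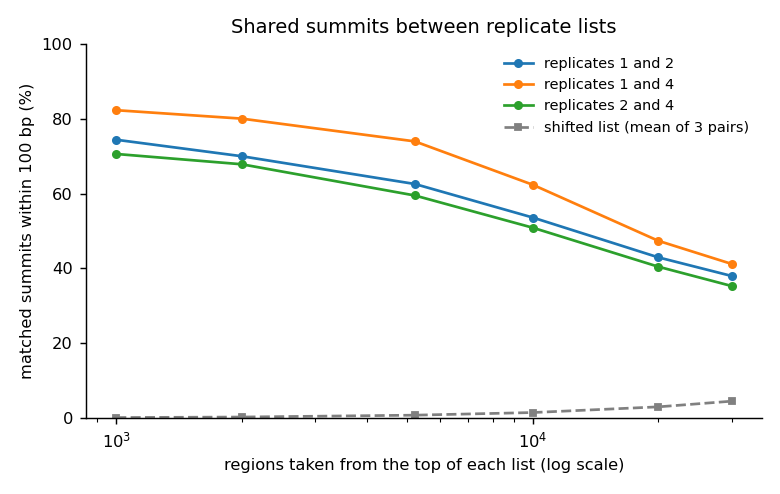
Share of summits (%) matched within 100 bp between pairs of replicates, by the number of strongest regions taken from each list, with the mean for randomly shifted lists. The pair of replicates 1 and 4 lay highest, at 74.0% for 5208 regions, where the shifted lists matched at 0.787%; the shifted mean rose from 0.147% for 1000 regions to 4.52% for 30000.

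The optimal list was the top of the pooled list. All 5208 optimal peaks were the same regions at the same ranks as the first 5208 pooled regions, whose signal ended at 148.2. None of the 24792 pooled regions past that rank had its summit within 100 bp of an optimal summit. Both sets are parts of the same pooled list, so this count describes how summits are spaced in it, not what the rate threshold kept. By at least 1 bp of interval overlap, 10.3% of the next 5208 pooled regions and 5.24% of the 5208 after those touched an optimal peak.

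Peaks were concentrated at promoters and nearly missing from coding sequence. Of the 5208 optimal summits, 2383 lay within 500 bp of the start site of a protein-coding gene (45.8%, 95% Wilson interval 44.4 to 47.1), against 11.5% of random positions, a ratio of 3.99. The share in the replicates was 46.9% ± 2.96 (SD, n = 3). Only 11 summits fell in coding exons (0.211% against 13.9%) and 41 in 3' untranslated regions (0.787% against 4.50%). Between genes lay 774 summits (14.9% against 30.0%), and in introns 1963 (37.7% against 39.3%). The 36 summits in 5' untranslated regions outside promoters (0.691% against 0.789%) did not pass the permutation test against random positions (adjusted p = 0.45). With promoters taken as 1000 bp wide this class did pass, at 0.154% against 0.454% (permutation, unadjusted p = 0.010). The median distance to a start site was 662.5 bp, against 4222 bp at random, with 943 peaks (18.1%) within 100 bp and 958 (18.4%) beyond 5000 bp. By two-sided permutation with 1000 random sets and Benjamini-Hochberg adjustment, the promoter, coding, 3' and intergenic shares had p = 0.0020, the smallest possible (adjusted p = 0.0030), and the intron share had an adjusted p of 0.031. Among the 5000 weakest pooled regions, 14.1% of summits lay in promoters and 7.24% in coding exons. The intron share rose above random positions when promoters were taken as 250 bp wide (43.3% against 40.9%).

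**Figure D2:**
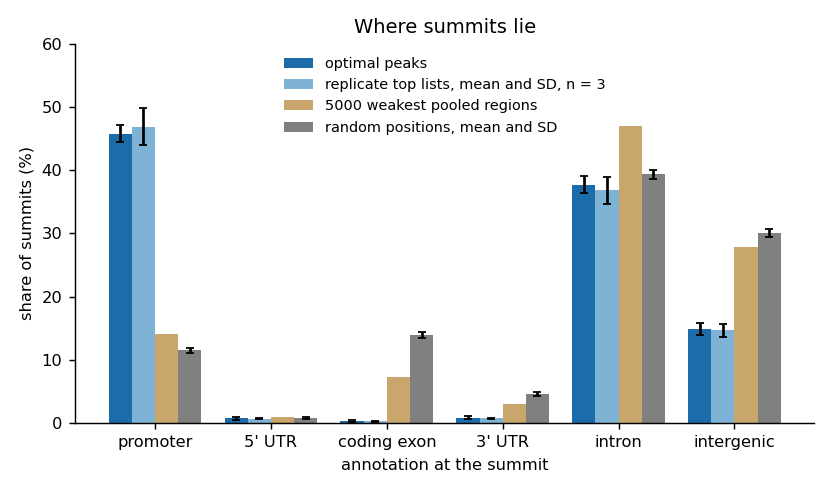
Share of summits (%) by annotation class, for the optimal list (bars with 95% Wilson intervals), the replicates (mean and SD, n = 3), the 5000 weakest pooled regions and random positions (mean and SD of 1000 sets). Promoters held 45.8% of optimal summits against 11.5% at random, and coding exons 0.211% against 13.9%.

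Chromosome 4, a small and largely heterochromatic chromosome, held few peaks. Its 9 peaks gave 6.68 per Mb (95% Wilson interval 3.51 to 12.7), against 37.7 in random placements by arm length, and the replicates gave 9.64 ± 3.23 (SD, n = 3). The X chromosome had 38.9 peaks per Mb and the other arms 37.2 (2R), 38.7 (3R), 40.4 (3L) and 41.1 (2L). No list, background regions included, held a region on Y, so Y could not be assessed. The share on X was 17.6%, against 17.1% by length (permutation, adjusted p = 0.47), and 17.1% ± 1.08 in the replicates (SD, n = 3). It was 17.7% in the dm3 optimal list, and 19.1% among peaks matched in all 3 replicates, where it passed (permutation, adjusted p = 0.017). Two-sided permutation gave p = 0.0020 for chromosome 4, the smallest possible (adjusted p = 0.0070), and an adjusted p of 0.014 for 2L and 0.031 for 3L. These placements included Y, which lowers the number placed on the other arms. With Y left out, neither 2L nor 3L passed (permutation, adjusted p = 0.20 for each), and chromosome 4 still did (0.012).

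Genes of the cytosolic ribosome, which makes up the translation machinery, stood out from every other group examined. A promoter peak was found at 75 of 88 ribosomal protein genes (85.2%, 95% Wilson interval 76.3 to 91.2), against 20.2% of the other protein-coding genes, and at 82.6% ± 0.656 in the replicates (SD, n = 3). Among the strongest were those at RpS27 (3R, 25247339 to 25247733, signal 1952), RpL7 (signal 1757) and RpL23A (1265). The 13 genes without a promoter peak were RpL21, RpL40, RpL6, RpS13, RpS24, RpS3, RpS10a, RpS15Ab, RpL37-2, RpS5b, RpL10Aa, RpS19b and RpS28a. Their like-named RpS10b, RpS15Aa, RpL37-1, RpS5a, RpL10Ab, RpS19a and RpS28b had one. Mitochondrial ribosomal protein genes, which serve translation inside mitochondria, had a promoter peak at 30 of 73 (41.1%, interval 30.5 to 52.6), with 36.1% ± 4.19 in the replicates (SD, n = 3). Their strongest peaks were at mRpS10 (signal 2557), mRpL41 (2500.4), mRpS23 (2168) and mRpL23 (1612). Of the 30 mitochondrial ribosomal protein genes with a peak, 29 shared it with another gene whose start site lay within 500 bp of the summit, such as mRpS10 with Art3 and mRpS23 with CenG1A, as did 33 of the 75 cytosolic ones, such as RpS27 with Nup37. Over all 13945 protein-coding genes, 2870 had a promoter peak (20.6%), and 20.5% ± 0.624 in the replicates (SD, n = 3).

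Groups tied to nutrient sensing, autophagy, stress and growth held more promoter peaks than all other genes, but none of these 6 lists kept the call in every alternative. With peaks matched in all 3 replicates none of the 6 passed, nor did the mitochondrial ribosomal proteins. In autophagy and the lysosome, 16 of 35 genes had a promoter peak (45.7%), the strongest at Atg17 (signal 736), Atg2 (693), Atg4b (560.2) and Atg18a (533). Of these 16 peaks 12 were shared with a neighbour, among them those named, with Xe7, CG12093, Hibch and ERR. Among bZIP factors it was 11 of 24 (45.8%), led by Atf3 (X, 1275264 to 1275741, signal 2002), REPTOR (1116), Irbp18 (890.4) and Pdp1 (705). In the nutrient list of TORC1 and insulin signalling it was 18 of 52 (34.6%), with the strongest at Sesn, which encodes sestrin (1416), sgg, which encodes the kinase GSK3 (1312), REPTOR and the forkhead factor foxo (659). The labels leave open that REPTOR itself carries the tag, so its peaks were not separated from those that extra copies of a tagged gene would give; without REPTOR the nutrient list did not pass (17 of 51, Fisher's exact test, adjusted p = 0.082) and bZIP factors did (10 of 23, 0.042). Cell cycle genes had 15 of 32 (46.9%), among them CycE (747), Dp, a partner of E2F (693), mei-41, the fly ATR kinase (495), and Mcm2 (447). The integrated stress and unfolded protein response had 10 of 23 (43.5%), with Hrd3 (1556), Xbp1 (491), Sec61alpha (394) and Nmdmc (348). Heat shock genes also had 10 of 23, with Hsp83, the fly Hsp90 (1337), Hsp27 (1118), Hsc70-5 (696) and the co-chaperone stv (632). Peaks were shared with a neighbour at 5 of the 10 stress response genes, 6 of the 15 cell cycle genes and 3 of the 10 heat shock genes. The same held for 6 of the 18 nutrient genes and 2 of the 11 bZIP genes. Among the named genes these were Hrd3, Sec61alpha, Nmdmc, mei-41, Mcm2, Hsc70-5, Sesn and Irbp18.

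None of 179 chemosensory receptor genes, which act in adult and larval sense organs, had a promoter peak, which allows a share of up to 1.68%. Of Hox and segmentation genes 6 of 59 had one (10.2%), of neuronal differentiation genes 3 of 27 (11.1%), of proteasome genes 5 of 48 (10.4%), and of oxidative phosphorylation genes 18 of 87 (20.7%). The shares were 15.8% for core splicing genes (3 of 19), 32.3% for tRNA synthetases (10 of 31), 37.5% for the circadian clock (6 of 16), 33.3% for Notch and E(spl) genes (6 of 18) and 31.8% for the germline (7 of 22). They were 13.8% for muscle (4 of 29), 11.5% for fat body and hemocytes (3 of 26), and 12.5% for midgut, epidermis and trachea (3 of 24).

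By Fisher's exact test (two-sided, Benjamini-Hochberg over 21 lists), 9 lists passed, 8 higher and 1 lower, as many as with unadjusted p. The adjusted p was 2.1e-37 for ribosomal proteins (odds ratio 22.8), 1.6e-17 for chemosensory receptors, 0.00043 for mitochondrial ribosomal proteins (2.71), 0.0040 for the cell cycle (3.42) and 0.0043 for autophagy (3.26). It was 0.017 for bZIP factors (3.27) and 0.038 for the nutrient (2.05), stress response (2.98) and heat shock lists (2.98). Against 10000 random lists matched on gene length and number of start sites, 6 lists passed, 4 of them in both tests. These were ribosomal proteins (matched lists 22.9%), mitochondrial ribosomal proteins (11.6%) and chemosensory receptors (17.7%), each with permutation p = 0.00020, the smallest possible (adjusted 0.0014), and autophagy (24.8%, adjusted p = 0.041). Hox and segmentation (26.1%, permutation, adjusted p = 0.019) and neuronal genes (34.1%, 0.041) were below their matched lists. The nutrient list (27.3%, permutation, adjusted p = 0.38), the cell cycle (0.0504), bZIP factors (0.094), heat shock (0.098) and the stress response (0.18) did not pass it. With peaks matched in all 3 replicates, 2 lists passed, ribosomal proteins and chemosensory receptors. Genes are not independent replicates, and a peak between divergent genes counts for both. Genes with the start site of another gene within 1000 bp had a promoter peak in 32.2% of cases and the rest in 11.8%. With random lists also matched on such a neighbour, 4 lists passed, namely ribosomal proteins (matched lists 25.1%), mitochondrial ribosomal proteins (18.6%), chemosensory receptors (12.6%) and bZIP factors (21.7%, permutation, adjusted p = 0.036). Autophagy (29.7%, permutation, adjusted p = 0.13), Hox and segmentation (0.21) and neuronal genes (0.057) did not.

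**Figure D3:**
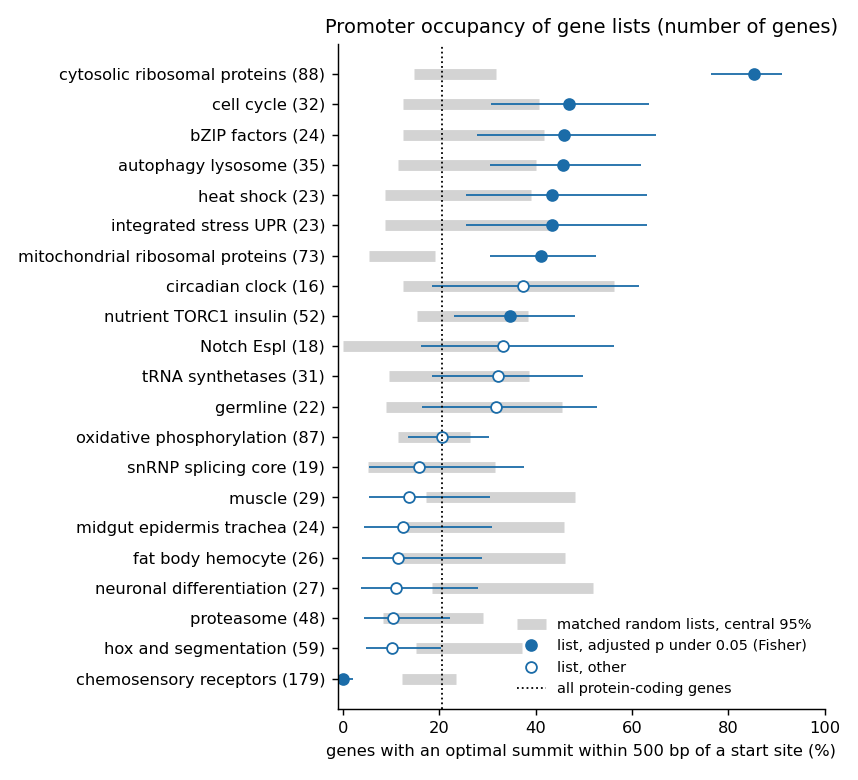
Share of each list's genes (%) with an optimal summit within 500 bp of a start site, with 95% Wilson intervals as lines and, as grey bars, the central 95% of random lists matched on gene length and number of start sites. Filled points passed Fisher's exact test after adjustment, the dotted line marks all protein-coding genes at 20.6%, and ribosomal protein genes reached 85.2%, and chemosensory receptors 0%.

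The genes of the tagged protein and of its partner differed in what the lists held. Within 5 kb of REPTOR (3R, 24557368 to 24582864, minus strand) lay 9 optimal peaks, 7 of them inside the gene. The strongest, at 24572458 to 24572823, ranked 174 in the optimal list, and its match ranked 195, 94 and 240 in replicates 1, 2 and 4. Of 13945 genes, 53 had as many summits inside, and the median was 1 for 382 genes of similar length. Within 5 kb of REPTOR-BP (2L, 10264125 to 10265229, plus strand) the optimal list, the pooled list and replicates 1 and 4 held no region, whereas replicate 2 held 14, the strongest with a signal of 65.7 at rank 3457. The stretch without any summit around REPTOR-BP ran for 56.8 kb in replicate 1, 60.1 kb in replicate 4 and 54.9 kb in the pooled list, against a median spacing of 1.86, 1.98 and 1.68 kb. As long a stretch occurred 87, 91 and 81 times among the 29994 spacings of these lists. In replicate 2 the same spacing was 1.05 kb. Whether this stretch was left out when the other lists were called is not given in the sources used here, so the counts of 0 there need not mean a lack of signal.

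**Figure D4:**
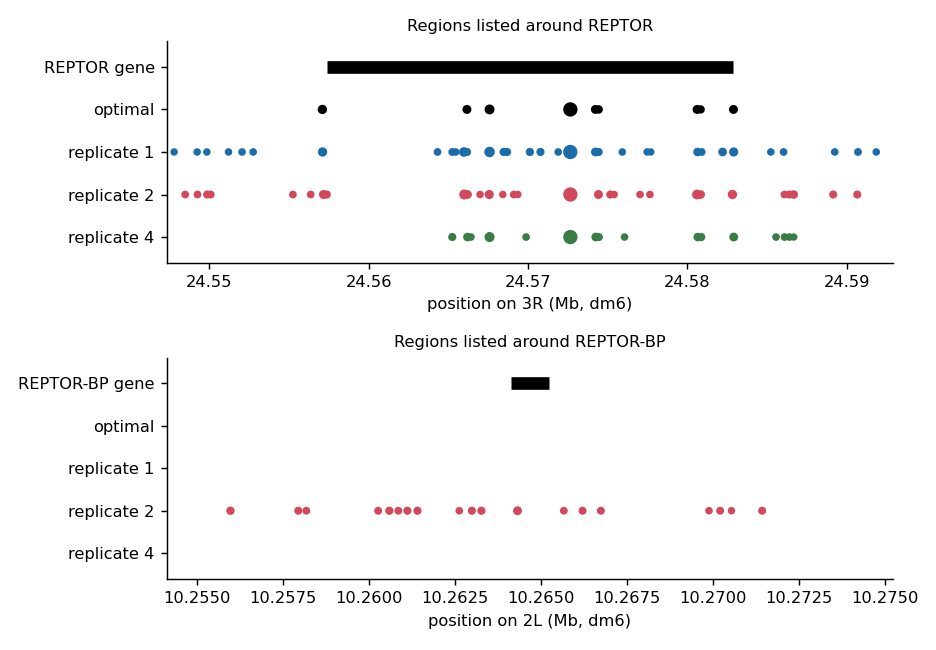
Regions listed around REPTOR and REPTOR-BP, as points at their summits (Mb on the arm), with point area rising with signal relative to the highest in the same list among the regions drawn. Near REPTOR-BP only replicate 2 held regions, 14 of them within 5 kb.

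Peak summits were rich in A and T and rarely carried the sites known for bZIP factors. The windows of 101 bp at summits had 34.8% G and C, against 43.6% in the flanks of the same peaks, a drop of 8.78 percentage points ± 0.172 (SE over 5208 peaks). The drop was 8.53, 5.76 and 9.44 points in the strongest 5208 regions of replicates 1, 2 and 4. The palindromic cAMP response element TGACGTCA, bound by many bZIP dimers, was in 9 summit windows (0.173% against 0.230% in flanks), and its core TGACG was lower at summits (6.72% against 9.84%, ratio 0.683). The DRE element TATCGATA of housekeeping promoters was in 1.5% of summit windows against 0.298% of flanks (ratio 5.03; replicates 5.25 ± 0.839, SD, n = 3), but its ratio was 0.25 in peaks outside promoters, where it did not pass. The Motif 1 core GGTCACAC, another promoter element, had a ratio of 3.8, the TATA box TATAAAAG 2.08 and the FOXO site TGTTTAC 1.76. The GAGA repeat was lower at summits (1.19% against 3.18%, ratio 0.375). None of these ratios is corrected for the lower G and C at summits.

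By the exact sign test with the larger p of both flanks (two-sided, Benjamini-Hochberg over 16 motifs), 6 motifs passed, 4 higher and 2 lower, against 7 with unadjusted p. The adjusted p was 6.4e-11 for GAGA, 4.6e-10 for DRE, 1.1e-07 for TGACG, 3.0e-06 for FOXO, 2.6e-05 for Motif 1, 0.021 for TATA and 1 for the full response element. The other motifs did not pass: AP-1 (ratio 1.02), PAR and C/EBP (1.45), ATF4 (0.784), XBP1 (0.580), the Myc E-box (0.671), Zelda (0.647), CAGCTG (0.817), CTCF (0.491) and the shuffled response element (0.889). Against other arrangements of the same bases, 0 of 14 motifs passed and 2 had an unadjusted p under 0.05, namely DRE (exact share of arrangements as extreme, p = 0.010) and Motif 1 (p = 0.0060), each with an adjusted p of 0.071. Median ratios of the arrangements were 0.768 for TGACG, 0.438 for GAGA, 2.01 for TATA and 1.30 for FOXO. Each lay in the direction of its motif, so the calls for these motifs were not separated from the drop in G and C. The medians were 1.61 for DRE and 0.619 for Motif 1, further from the ratios of those motifs. Of 2080 hexamers, 1558 passed Fisher's exact test with Benjamini-Hochberg adjustment, 531 higher and 1027 lower. That test treated summit and flank windows of the same peaks as independent. It had no control for base composition, so these calls were not separated from the drop in G and C. The highest ratios were for ATATTA (2.57), TACTAA (2.55), TATTAA (2.38), ATAGTA (2.38) and AATATT (2.38), and the lowest was for GGAGGA (0.213).

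Stronger peaks were more often at promoters. In the strongest of 5 equal bins by signal, 58.8% of summits lay in promoters, against 37.5% in the weakest (odds ratio 2.38, Fisher's exact test, adjusted p = 4.0e-21). Of 17 features compared this way, promoters and 16 motifs, 1 passed. With 10 bins the promoter shares were 63.1% and 35.5%.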

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

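The count of regions off the main arms in the dm3 lists, which the comparisons above use only for shares per arm, was chosen after the lists were seen. The dm3 lists held regions on sequence that the dm3 build names as heterochromatic or unplaced, apart from the main arms, whereas the dm6 lists held 0 regions off the main arms. The dm6 arms themselves include heterochromatic sequence. There were 44 such regions in the pooled dm3 list, 80 in replicate 1, 12 in replicate 2 and 164 in replicate 4, each list having 30000 regions. They drew attention as regions in lists outside the main measurement, above the 3 counts that an observed 0 allows. The 0 in dm6 is no background level for them, because the dm6 arms include such sequence. These lists also hold peaks and background together. The optimal dm3 list of 4653 peaks held 1. No technical or biological explanation was tested for them.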

How the results depend on the processing

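Chosen after the data were seen were the alternatives with peaks matched in replicates 1 and 4, arrangements of the same bases, arm Y left out, lists matched also on a neighbouring start site, REPTOR left out, the weakest pooled regions, and replicates left out for arms and rank agreement. Of 532 values under the alternatives, 433 kept their direction and their side of the threshold or moved by less than the replicates' spread, 51 no longer passed, 7 newly passed, 5 moved further and 36 changed direction. The cause was not tested unless stated.

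Replicate overlap stayed far above shifted lists in every alternative run, between 38.2% and 75.8%, and between 59.5% and 74.0% with a replicate left out. Rank agreement ranged from 0.634 to 0.811 with a replicate left out, the highest without replicate 2. The promoter share stayed above random positions throughout. The intron share reversed to 43.3% with 250 bp promoters, against 40.9% of random positions. The narrower definition passes bases to introns in both, but the peaks rose more, from 37.7%, than random positions did, from 39.3%.

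The share on X was 19.1% in peaks matched in all 3 replicates and then passed (permutation, adjusted p = 0.017, range over alternatives 0.017 to 0.98). The 3R share fell below expectation at 23.1% in those peaks and, at 23.8%, with Y left out, without passing anywhere.

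Ribosomal protein and chemosensory genes passed in every alternative run. The number of lists that passed was 5 with 250 bp promoters, 4 with the stronger 2604 peaks, 2 with peaks matched in all 3 replicates, both having fewer peaks, and 4 against lists also matched on a neighbour. The nutrient list no longer passed at 28.8% (250 bp), 19.2% (stronger peaks), 19.2% (all 3 replicates), 25% (replicates 1 and 4), 34.6% (against either kind of matched lists) and 33.3% (without REPTOR). Lists that passed in no setting changed side at 21.8% (1000 bp), 9.20% (stronger peaks), 9.20% (all 3), 14.9% (1 and 4) and 20.7% (neighbour) for oxidative phosphorylation; 24.1% (1000 bp), 41.4% (gene bodies with 2 kb), 13.8% (stronger) and 13.8% (all 3) for muscle; 33.3% (1000 bp) for midgut; 31.8% (neighbour) for germline; and 15.8% (stronger) and 15.8% (1 and 4) for splicing.

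DRE, higher at all summits, reversed to a ratio of 0.25 outside promoters without passing there. Motifs past the threshold in neither setting changed side at 1.71 (25 bp windows), 1.38 (all 3 replicates), 1.18 (outside promoters) and 1.06 (arrangements) for the shuffled element; 0.833 (100 bp), 0.931 (all 3) and 0.897 (outside promoters) for AP-1; 1.00 (stronger) and 0.881 (arrangements) for PAR and C/EBP; and 1.07 for ATF4 outside promoters. Against arrangements the ratios changed to 1.11 for XBP1, 1.07 for the Myc E-box, 1.30 for CAGCTG and 1.35 for CTCF. With 10 bins the difference from top to bottom bin, called in neither setting, changed sign to −0.192 percentage points for the full response element, −0.192 for XBP1, −1.53 for FOXO, −0.191 for Zelda and −0.575 for CTCF. Depth could not be varied, since the lists hold no reads.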

Other observations

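The tests of replicate 2 at REPTOR-BP and of Polycomb and trithorax genes were chosen only after the result was seen. The other tests below were not part of the plan either. They were set for patterns already seen in the data, but before their own results.

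Ribosomal protein promoters held peaks far more often (85.2%) than other genes. Against gene length and number of start sites as the cause, the upper end of the 95% range of matched lists was 31.8%. For heavy transcription of any kind, 14 of 290 tRNA genes had a summit within 500 bp (4.83%, Wilson interval 2.90 to 7.94). Whether peaks could be called at such genes was not checked, and 0 of 99 rRNA genes had a summit. The tRNA share therefore cannot decide on heavy transcription. Signal over abundantly transcribed protein-coding genes stays open. Of 34 abundant housekeeping genes, 18 had a promoter peak (52.9%, interval 36.7 to 68.5), among them Eno (signal 1593), Fer1HCH and Fer2LCH (1427). Against all other genes the odds ratio was 4.36 (Fisher's exact test, two-sided, unadjusted p = 3.0e-05). Random lists matched on gene length and start sites gave 34.1% (permutation, unadjusted p = 0.029). Other lists of general cell functions had lower shares, with 10.4% for the proteasome, 15.8% for core splicing and 20.7% for oxidative phosphorylation. The proteasome and oxidative phosphorylation lists also count like-named genes without a peak, such as Rpn13R beside Rpn13 and ND-24L beside ND-24. The cytosolic ribosomal list holds some as well. These shares therefore depend in part on how the lists were built. The share was 27.8% for translation factors, 32.3% for tRNA synthetases and 41.1% for mitochondrial ribosomal proteins. Expression was not analysed, so how these lists differ in transcription is unknown. A part of the pattern may come from transcription level rather than from the tagged protein. Without an untagged control no biological explanation was tested.

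Over REPTOR-BP, in the 20 kb window of the gene (2L, 10260001 to 10280000), replicate 2 had 17 regions and replicates 1 and 4 had none, and the next highest excess in 6690 other windows was 13. The highest excess of replicate 2 was 13 among 719 windows with a similar coding share. At REPTOR-BP the excess equals the full count of replicate 2, since replicates 1 and 4 held none. Those counts of 0 may come from the calling, so the excess cannot decide on a general surplus in gene-dense sequence. A nearby window (10220001 to 10240000) had 16 regions in replicate 2, and 7 and 3 in replicates 1 and 4. Among 791 other windows without regions in replicates 1 and 4, replicate 2 held at most 11. A wider stretch of the arm stays open, since 5 of 8 neighbouring windows lay above the 95th percentile of the excess. Extra copies from a tagged transgene could not be separated from it and cannot be told apart here, because the highest excess elsewhere was 13 but the neighbours were also raised. A stretch left out by the authors when replicates 1 and 4 were called also stays open and was not tested.

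Summits were richer in A and T than their flanks. A preference of the libraries or the caller that acts on all regions alike would also show in weak regions. There the drop in G and C from flank to summit was −1.74 percentage points ± 0.173 (SE, 5000 weakest pooled regions). A preference that raises the signal of such sequence cannot be decided this way, because the weak regions were picked by their low signal. Promoter sequence alone did not account for it, as the drop was 7.85 points ± 0.218 (SE) in 2825 peaks outside promoters. With no untagged control, a preference that acts on open chromatin alone was not tested, and no biological explanation was tested.

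Promoters with a peak may differ in sequence from those without. Within 250 bp of the start site the DRE element was found for 366 of 2870 genes with a promoter peak (12.8%). Without a peak it was 977 of 11075 genes (8.82%, odds ratio 1.51, Fisher's exact test, two-sided p = 7.3e-10). The Motif 1 core was found for 11.7% and 7.47% (odds ratio 1.65, Fisher's exact test, p = 1.2e-12). Of the 2870 genes, 1625 shared their peak with another gene, so 1 promoter can count more than once. Both p-values treat genes as independent and may be too small. The 2 groups of genes were not matched on neighbouring start sites or number of start sites.

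Polycomb and trithorax genes, which keep genes silent or active, had a promoter peak at 11 of 24 (45.8%, odds ratio 3.27, Fisher's exact test, two-sided p = 0.0047). Against matched lists (28.2%) the permutation p was 0.091, so the hypothesis that they are preferred may rest on their length and start sites. Examples were brm (signal 1285) and E(z) (970.4). For translation factors, a hypothesis set from the ribosomal result, 15 of 54 had one (27.8%, odds ratio 1.49, Fisher's exact test, p = 0.18), led by eIF6 (1919) and eIF4EHP (1850.3), and the count did not decide it.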
